A study of Mus musculus with 4 samples.

How the data were processed

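DNA methylation was measured by enhanced reduced representation bisulfite sequencing, in which genomic DNA is cut with a restriction enzyme that favours CpG-rich sequence, treated with bisulfite and sequenced. Per the labels, the DNA came from the brains of C57BL/6 mice and from cells isolated by fluorescence-activated sorting. One group was sorted on GFP driven by Pdgfra at postnatal day 2 (P2 progenitors), and the other on GFP driven by Plp1 at postnatal day 18 (P18 oligodendrocytes). Each group held 2 libraries, which the labels call biological replicates and number 2 and 3. Age, cell type and reporter line changed together, so these 3 factors could not be separated.

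Each library had 1 deposited table with a row per cytosine, its strand, its coverage as a raw count of reads, and the percent of reads read as C (methylated) and as T (unmethylated). The submitters' processing notes name methylKit and the mouse build mm10. The aligner, the methylation caller and their versions are not given in the sources used here. The deposited names of the tables call them normalized, but the coverage values were whole-number counts that gave a whole number of methylated reads at 100% of cytosines, within 0.01 reads. Coverage was therefore used as read counts, and methylated and unmethylated counts were the deposited coverage multiplied by the deposited percent. At up to 0.494% of the cytosines of a library the percent read as C and the percent read as T summed to less than 100, and the remaining reads were left out.

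Cytosines covered by at least 10 reads in all 4 libraries were kept (1318952 cytosines). Both strands were kept as separate cytosines. Of the kept forward-strand cytosines, 28.1% had their reverse-strand partner among the kept ones. The annotation at hand was a RefSeq gene table of GRCm38.p6, whose coordinates are those of mm10. It gives gene starts and ends but no strand, exons or CpG islands, so promoters could not be defined as planned. In their place, for each protein-coding gene, the window of 1 kb either side of whichever annotated end held more kept cytosines was used, and is called the CpG-rich gene end. The median methylation of these windows was 0.231%, and 88.9% of them lay under 20%. A gene interior was the annotated gene without the 1 kb next to each end. Gene ends and interiors needed at least 5 kept cytosines, and 1 kb tiles at least 3. Where genes had windows with identical counts, each such window was counted once in the gene lists.

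The groups were compared feature by feature with a quasi-binomial logistic regression on methylated and unmethylated counts, written in R 4.3.3 with the data.table package, version 1.17.8. The Pearson dispersion, which has 2 residual degrees of freedom, was moderated across features with limma 3.58.1 (squeezeVar, trend on log coverage) and not allowed below 1. P-values came from an F test and were adjusted by Benjamini-Hochberg within each kind of feature. A feature was called at an adjusted p under 0.05 and a difference of at least 25 percentage points for cytosines or 10 percentage points for tiles, gene ends and interiors. Differences are P18 minus P2 of the library means. The gene lists were myelin and mature oligodendrocyte, oligodendrocyte progenitor, inhibitors of oligodendrocyte differentiation, cell cycle and DNA replication, cholesterol and sterol synthesis, fatty acid and sphingolipid metabolism, neuronal identity and synapse, neurogenic transcription factors, astrocyte, microglia and immune, endothelial and mural, Hox, imprinted, germline, DNA methylation machinery, histone modifiers, clustered protocadherins, Notch and Wnt signalling, and cytoskeleton and process outgrowth. All listed symbols were found in the gene table except 2 imprinted genes and 1 protocadherin. They were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, on log2((methylated + 1)/(unmethylated + 1)). At the preset correlation camera takes its degrees of freedom from the number of genes, so its p does not measure spread between libraries. With an estimated correlation it uses the 2 residual degrees of freedom of the libraries. Comparisons of a single value used exact two-sided permutation tests, which cannot go below p = 0.333 with 2 libraries against 2. Preparation of the tables and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

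The tests, thresholds, 19 gene lists and the rule for named genes were set before the data were examined. The rule took the 12 largest gains and 12 largest losses among called gene ends whose libraries did not overlap between the groups, leaving out provisional gene names, and from each list the 4 gene ends with the smallest p. It also took the 5 largest gains and 5 largest losses among gene interiors, and a fixed set of lineage and methylation-enzyme genes. Other interiors of list members were picked from the called members after their values were seen, by no fixed rule. The alternatives were other coverage minimums, a logistic test without overdispersion, limma on the log ratio, a replicate block, each library left out, no sex chromosomes, no cytosines of extreme coverage, other difference thresholds, merged strands, other windows and tile sizes, and other gene-list tests. Alternatives chosen after seeing the data were the CpG-poorer or both gene ends, a dispersion prior from features at 10 to 90% methylation, a limit on the change in depth, a background of cytosines with room to change, the mean over each library's own cytosines at any coverage, and counting every gene of a list.

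The test was tried on simulated beta-binomial counts with the real coverages, in which 100 features of each size and kind were changed. Each feature of a kind was given the same overdispersion, the median over all features (0.000284 for gene ends). Only features of intermediate methylation were changed. Real dispersions differ between features, so the recovered shares and false calls hold for that setting only. For gene interiors (11332 features), 99 of 100 changes of 15 points and 100 of 100 of 30 points were recovered, with 0 false calls. For gene ends (13419 features), 95 of 100 and 100 of 100 were recovered at those sizes, with 0 false calls. For 1 kb tiles (110461 features), 29 of 100 and 97 of 100 were recovered, with 2 false calls. For single cytosines (1318952 features), 6 of 100 changes of 30 points and 53 of 100 of 45 points were recovered, with 0 false calls.

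Coverage per library, summed over cytosines, was 82364910 to 88202904, and the median coverage of the kept cytosines was 49 to 53 reads. Read numbers of a library, window or locus are such sums, so a read that covers several cytosines is counted at each. The reads carry no molecular identifiers that were used here, so counting intervals (95%, exact Clopper-Pearson) cover counting error only. They also take these counts as independent.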

Results

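Methylation was profiled in oligodendrocyte progenitors, the dividing precursors of the myelin-forming cells of the brain, and in oligodendrocytes, the cells that differentiate from them. The progenitors were sorted at postnatal day 2 (P2, replicates 2 and 3) and the oligodendrocytes at postnatal day 18 (P18, replicates 2 and 3). Coverage summed to 88202904 and 84862932 over the 3322441 and 3934862 cytosines of the P2 libraries. In the P18 libraries it summed to 82364910 and 87779952 over 3939894 and 3855461 cytosines. All coordinates are on GRCm38.

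The first comparison asked whether the mean level of methylation differed between the 2 stages. Over the 1318952 shared cytosines the mean level was 31.0% ± 0.102 (SD, n = 2) in P2 progenitors and 31.2% ± 0.0592 (SD, n = 2) in P18 oligodendrocytes. Cytosines between 20 and 80% made up 16.2 and 15.8% of cytosines in the P2 libraries and 14.6 and 14.7% in the P18 libraries. Those above 80% made up 23.0% ± 0.356 in P2 and 24.2% ± 0.191 in P18, and those below 20% made up 61.0% ± 0.0218 and 61.2% ± 0.0894. In each of these measures both libraries of one group lay above both of the other, and the exact permutation test gave p = 0.333, the smallest possible with n = 2. The sign of the mean difference depended on which cytosines were averaged: it was 0.270 points over shared cytosines, -0.414 points over each library's own cytosines with at least 10 reads, and 0.845 points over its own cytosines at any coverage, a setting chosen after seeing the data. Over own cytosines the groups overlapped. The P2 and P18 libraries stood at 32.4 and 31.6% against 31.4 and 31.8% with at least 10 reads. At any coverage they stood at 48.4 and 51.4% against 50.7 and 50.7%.

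The second comparison asked which single cytosines differed. Of 789714 cytosines that could be tested, 23433 were called. Methylation was lower in P18 oligodendrocytes at 15186 of them (64.8%), with a median change of -42.6 points, and higher at 8247, with a median of 34.5 points. Their place in the genome depends on the background, because a cytosine below 25% in P2 cannot fall by 25 points and many at gene ends lie there. Gene interiors held 66.9% of the cytosines that fell and 58.2% of those that rose. Against all tested cytosines, as planned, their odds ratios were 2.49 and 1.70; against cytosines whose P2 level left room for the change, a background chosen after seeing the data, they were 1.86 (95% CI 1.80 to 1.93) and 2.22 (CI 2.12 to 2.32). Windows around gene ends held 5.87% of the cytosines that fell, against 23.1% of all tested (odds ratio 0.204) but 6.79% of those with room to fall (odds ratio 0.852, CI 0.795 to 0.913), so most of their shortage came from the low starting level. The same holds for dense stretches, with 10 or more tested neighbours within 100 bp, whose odds ratio among the cytosines that fell went from 0.104 to 0.649. Among those that rose, the ratios went from 0.393 to 0.199 for gene ends and from 0.439 to 0.210 for dense stretches. Fisher's exact test treats neighbouring cytosines as independent, which makes its intervals too narrow. Of the cytosines that fell, 33.4% lay above 80% in P2 and 66.6% between 20 and 80%. Of those that rose, 35.1% started below 20%. Leaving out any 1 of the 4 libraries left no cytosine called by the same test. A difference of at least 25 points in the same direction was kept by 21085 to 21630 of the 23433. In 23418 of the 23433 both libraries of one group lay above both of the other, so their direction could not reverse. The calls were also chosen for a large difference in the same libraries, so the kept share does not measure their stability. With a dispersion prior taken from partly methylated features, an alternative chosen after seeing the data, 0 to 5475 were called with a library left out and 19705 with all 4.

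In fixed 1 kb tiles, 7892 of 109275 tested tiles were called, 4651 lower and 3241 higher in P18 oligodendrocytes. The largest falls of all, with differences of -86.1, -84.6 and -84.1 points, were in tiles that overlap the pseudogenes Gm45405 and Gm8497. Tiles in Mbp, Gpr37 and Acaca were among the other large falls. The tile at chromosome 18, 82567001 to 82568000, inside Mbp (myelin basic protein, a major structural protein of myelin), went from 90.2 and 91.9% in the P2 libraries to 18.2 and 18.1% in the P18 libraries. A tile in Gpr37 (chromosome 6, 25688001 to 25689000), which encodes a receptor made by oligodendrocytes, went from 86.9 and 80.8% to 10.9 and 5.13%. A tile in Acaca (chromosome 11, 84207001 to 84208000), acetyl-CoA carboxylase, the entry enzyme of fatty acid synthesis, went from 71.4 and 87.9% to 3.20 and 11.2%. This tile held 4 cytosines at a P18 to P2 depth ratio of 1.41, and it also overlaps the pseudogene Gm31074. Among the largest gains, a tile in Tcf7l2 (chromosome 19, 55896001 to 55897000), a transcription factor of the Wnt pathway used in oligodendrocyte differentiation, rose by 63.8 points, from 17.1 and 13.7% in the P2 libraries. A pair of tiles in Mir9-3hg (chromosome 7, 79509001 to 79510000 and 79512001 to 79513000), the host transcript of the neural microRNA miR-9, rose by 61.3 and 52.3 points. These tiles were picked from the 20 largest gains and 30 largest losses after their values were seen. The count of tiles was 14256 without overdispersion (7322 lower) and 4583 with limma on the log ratio (3189 lower). With the dispersion prior from partly methylated features it was 7712. By the planned test no tile was called with any 1 library left out. A difference of at least 10 points in the same direction was kept by 7483 to 7633 of the 7892. In 7891 of the 7892 the libraries of the groups did not overlap, so their direction could not reverse. These tiles were also chosen for their difference in the same libraries, so the kept share does not measure their stability.

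The third comparison asked which genes changed inside their annotated bodies. Of 11317 gene interiors tested, 829 were called, and 651 of them (78.5%) were less methylated in P18 oligodendrocytes. Several genes of the myelin sheath fell. Mog (myelin oligodendrocyte glycoprotein; chromosome 17, 37011741 to 37022397) fell from 87.0% ± 3.49 to 25.3% ± 1.24 (SD, n = 2 each; adjusted p = 2.85e-09). Mobp, which encodes another myelin protein, fell from 75.5% ± 2.38 to 27.9% ± 2.41 (adjusted p = 3.72e-07). The Mog and Mobp values rest on 7 and 5 kept cytosines, a small part of each interior. Cnp, a myelin enzyme, fell from 57.8% ± 0.332 to 15.5% ± 4.08 (adjusted p = 2.85e-09). Mbp fell from 53.8% ± 1.90 to 27.1% ± 0.654 over 116 cytosines (adjusted p = 1.35e-09), and Mag, the myelin-associated glycoprotein, from 67.8% ± 5.54 to 46.7% ± 1.58 (adjusted p = 4.07e-05). Sox10, a transcription factor needed throughout the lineage, fell from 13.4% ± 1.45 to 2.60% ± 2.57 (adjusted p = 0.000531).

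The 5 largest interior losses were at Cpt2, Tmod2, Mog, Dffb and Atp6v1b2. Cpt2, a mitochondrial carnitine palmitoyltransferase, fell from 87.9% ± 11.9 to 12.1% ± 2.92 over 5 cytosines with 109 to 199 reads per library. Tmod2, an actin-capping protein, fell from 86.2% ± 8.29 to 23.1% ± 3.22, and Dffb, a nuclease of programmed cell death, from 77.0% ± 2.96 to 17.3% ± 0.682. Atp6v1b2, a subunit of the vacuolar proton pump, fell from 76.4% ± 7.02 to 22.7% ± 8.89 over 6 cytosines with 98 to 201 reads per library. Tmod2 had 7 cytosines, 6 of them in a single 1 kb tile, and Dffb had 8, of which 6 lay in 1 tile. Of the 5 Cpt2 cytosines, 4 lay in 1 tile. The 5 largest gains were at Fgf15, Slitrk2, Pdlim4, Galnt12 and Trim17. Fgf15, a secreted growth factor of the embryonic brain, rose from 53.8% ± 2.63 to 87.5% ± 0.0440, and Slitrk2, a synaptic adhesion protein, from 30.4% ± 9.54 to 60.3% ± 0.750. These 2 interiors held 5 and 8 cytosines. Pdlim4 rose by 29.1 points, Galnt12 by 28.7 and Trim17 by 27.2. Adjusted p for these 10 interiors ranged from 2.50e-10 (Dffb) to 0.00204 (Slitrk2).

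The interiors of the methyltransferase genes Dnmt1, Dnmt3a and Dnmt3b, of Tet1, Tet2 and Tet3 and of the progenitor markers Pdgfra and Cspg4 were not called. Dnmt1, the maintenance methyltransferase, stood at 43.2% ± 4.62 in P2 and 45.1% ± 1.62 in P18, Dnmt3a at 14.6% ± 0.564 and 13.8% ± 0.807, and Dnmt3b at 90.4% ± 0.629 and 90.5% ± 4.23. Of the demethylating dioxygenases, Tet1 differed by -0.993 points (adjusted p = 0.790) and Tet3 by -2.64 (adjusted p = 0.286), while Tet2 differed by 7.41 points (adjusted p = 0.0407), under the 10-point threshold. Pdgfra and Cspg4 stood at 16.8% ± 0.0185 and 55.2% ± 2.10 in P2 and at 14.5% ± 0.707 and 54.0% ± 0.457 in P18. Myrf, a regulator of myelin genes, stood at 65.6% ± 4.95 in P2 and 57.4% ± 0.577 in P18 (adjusted p = 0.0520). Plp1 held no cytosine that passed the coverage minimum.

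**Figure D1:**
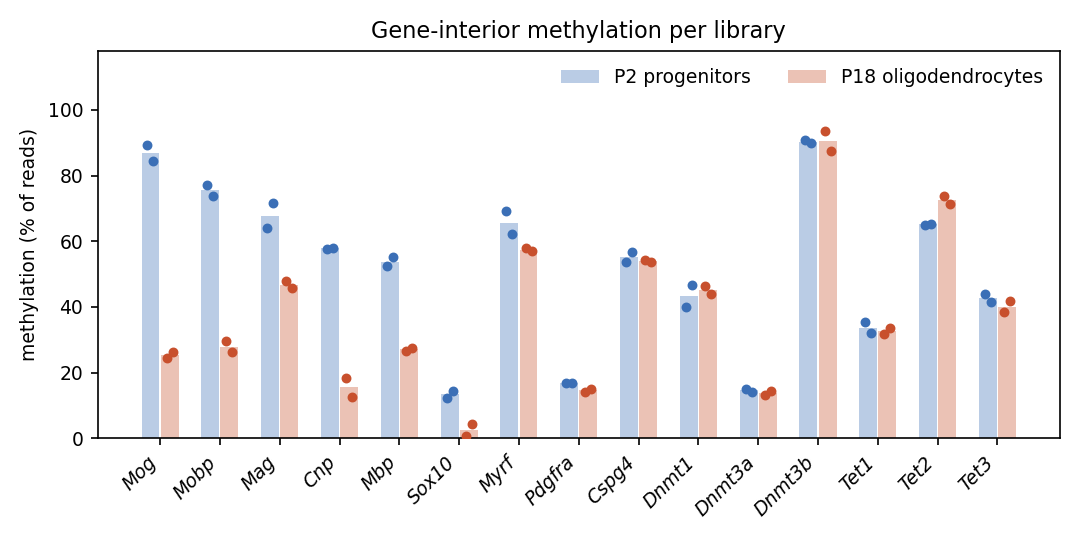
Methylation of the interiors of 15 genes, in percent of reads. Bars are the means of 2 libraries, points are the single libraries, and P2 progenitors are set beside P18 oligodendrocytes. Mog, Mobp, Mag, Cnp, Mbp and Sox10 were lower in both P18 libraries than in both P2 libraries, with Mog at 87.0 and 25.3%. Dnmt1, Dnmt3a and Dnmt3b were not called.

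Among the gene lists, the myelin and mature oligodendrocyte list had the largest share of called interiors. Of 40 measured, 24 were lower in P18 oligodendrocytes and 0 were higher, with a median difference of -14.5 points (camera, adjusted p = 1.19e-11; fry, adjusted p = 0.0264; adjusted p = 0.334 with an estimated correlation). Beyond the genes above, Ppp1r14a went from 55.3% ± 7.31 to 4.14% ± 0.155, Tspan2, a myelin tetraspanin, from 87.4% ± 1.09 to 36.9% ± 3.15, and Car2, a carbonic anhydrase, from 63.7% ± 9.33 to 19.3% ± 1.80. In the cholesterol and sterol synthesis list, 6 of 15 fell and 0 rose (camera, adjusted p = 0.000115; adjusted p = 0.334 with an estimated correlation). They included Hmgcs1, an early enzyme of the pathway, which went from 67.7% ± 0.273 to 38.7% ± 4.05, Sc5d, from 48.1% ± 1.82 to 11.7% ± 1.87, and Hmgcr, the rate-limiting enzyme, from 77.0% ± 3.83 to 64.0% ± 9.02. In the cytoskeleton and process outgrowth list, 9 of 42 fell and 0 rose (camera, adjusted p = 0.00224; adjusted p = 0.432 with an estimated correlation). Tubb4a, a tubulin abundant in oligodendrocytes, went from 91.8% ± 0.141 to 42.6% ± 2.40, and Tppp, a microtubule-bundling protein of these cells, from 48.3% ± 1.82 to 14.4% ± 0.501.

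The neurogenic transcription factor list moved the other way, from a low level. Its median level was 1.86% in P2 and 2.78% in P18. So near 0, a small change in points weighs heavily on the log ratio that camera tests. Of 46 interiors, 3 rose and 0 fell, with a median difference of 0.729 points (camera, adjusted p = 3.21e-07; adjusted p = 0.334 with an estimated correlation). The 3 were Otx1, from 11.5% ± 2.76 to 29.0% ± 4.97, Pax6, from 14.3% ± 1.17 to 27.0% ± 0.158 over 148 cytosines, and Dlx6, from 8.87% ± 2.15 to 21.0% ± 1.06, all of which encode patterning factors of the embryonic brain. The Hox list had 0 of 27 interiors called and a median difference of 0.636 points (camera, adjusted p = 3.89e-05, or 0.432 with an estimated correlation). Median Hox levels were also low, at 1.34% in P2 and 2.01% in P18. The clustered protocadherin list, cell-surface proteins of neuronal identity, had 0 of 32 called and a median of 1.91 points (camera, adjusted p = 0.0395; adjusted p = 0.825 with an estimated correlation), and its call was lost under several settings. Its adjusted p was 0.364 without P2 replicate 2, 0.274 without P18 replicate 2, 0.0853 and 0.0624 at coverage minimums of 5 and 20, and 0.0814 with every gene counted, a setting chosen after seeing the data.

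The other 13 lists were not called by camera for interiors (adjusted p = 0.0808 for germline genes to 0.856 for neuronal genes). Of 38 oligodendrocyte progenitor interiors, 5 fell and 1 rose, and 2 of 18 inhibitors of oligodendrocyte differentiation fell. Gpr17, a receptor of committed precursors held in both lists, went from 47.5% ± 2.43 to 13.3% ± 2.37. Fatty acid and sphingolipid genes went both ways, with 4 of 37 lower and 3 higher: Elovl7 fell by 30.3 points and Cers1, a ceramide synthase of neurons, rose from 19.3% ± 1.23 to 35.3% ± 1.19. Of 26 histone modifiers 3 fell (Brd4, Kat2b and Hdac1), of 37 neuronal identity and synapse genes 2 fell, and of 55 Notch and Wnt genes 2 rose (Fzd7 and Sfrp1) and 1 fell (Fzd3). In the cell cycle list 1 of 32 rose, in the DNA methylation machinery 1 of 17 rose (Smug1, a base-excision glycosylase), and in the germline list 2 of 12 rose. Astrocyte, microglia and vascular markers had no called interior: 0 of 28 for astrocytes, 0 of 16 for microglia and immune cells and 0 of 21 for endothelial and mural cells. Imprinted genes had 0 of 28, with a median level of 45.1% in P2 and 49.4% in P18. The medians and camera's direction were above 0 and the means below 0 for the inhibitor list (0.311 and -3.12 points) and the neuronal list (0.0898 and -0.571 points). Adjusted over the list alone, the counts of all 19 lists were the same except for cell cycle (0 higher), germline (3 higher) and fatty acid and sphingolipid genes (5 lower).

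**Figure D2:**
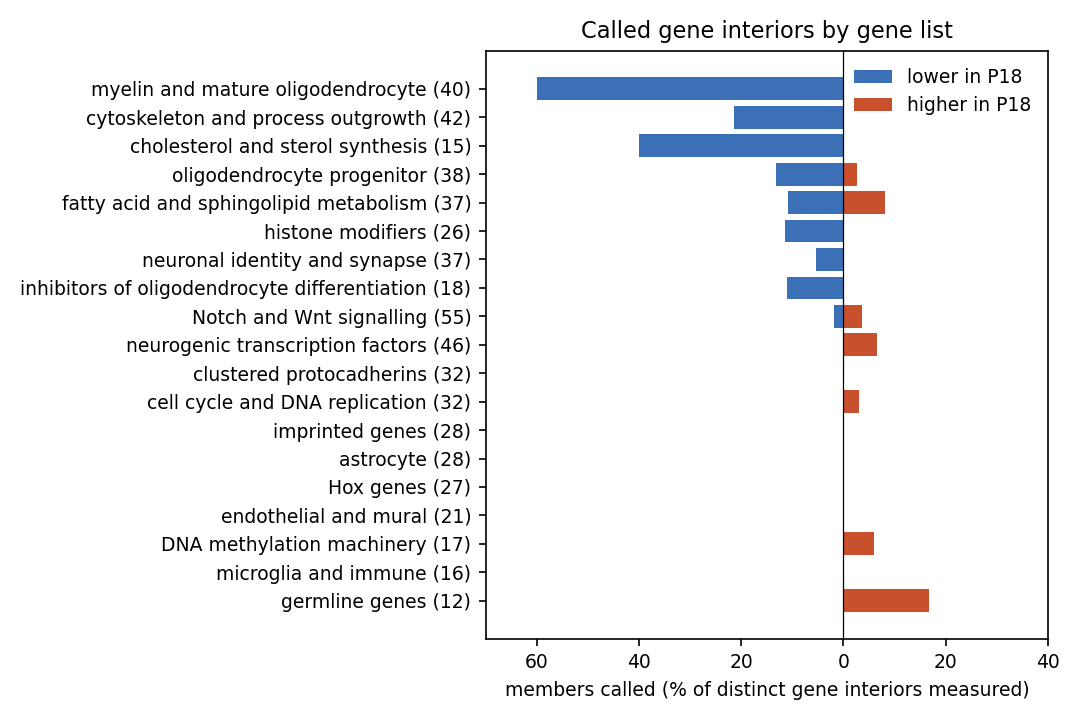
Share of the measured interiors of each of the 19 gene lists that were called lower (bars to the left) or higher (bars to the right) in P18 oligodendrocytes, in percent of distinct interiors, with the number measured in brackets. The myelin list has 24 of 40 lower and the cholesterol list 6 of 15 lower, both with 0 higher.

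Leaving out 1 library gave 639 to 729 called interiors in place of 829, and the myelin list kept a camera adjusted p of at most 3.36e-09 in each of these 4 fits. With a 25-point threshold 123 interiors were called, of which 112 were lower.

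The fourth comparison asked which CpG-rich gene ends, the windows used in place of promoters, differed. Of 13280 tested, 127 were called (123 distinct windows), 67 higher and 60 lower in P18 oligodendrocytes, and in each of the 127 both libraries of one group lay above both of the other. Of all CpG-rich ends measured, 88.9% were under 20% methylated. The 12 largest losses started at 46.6 to 85.5% in P2, and an end under 20% could not have fallen by as much. Without strand, it is not known which of the called windows lie at the start of a gene and which at its end. The largest losses were at Sptbn5, a spectrin (chromosome 2, 120040493 to 120042493), from 73.7% ± 0.970 to 24.6% ± 3.17 (SD, n = 2; adjusted p = 3.11e-05), and Egfl8, from 63.2% ± 5.01 to 15.6% ± 4.50 (adjusted p = 0.000170). Mag (chromosome 7, 30913922 to 30915922) fell from 48.7% ± 1.37 to 4.53% ± 0.0461 (adjusted p = 5.61e-05), and Mobp (chromosome 9, 120180488 to 120182488) from 79.0% ± 4.05 to 56.2% ± 0.407 (adjusted p = 0.00662). Gpr37l1, a receptor of astrocytes that lineage cells also express, fell from 51.2% ± 9.35 to 15.2% ± 0.349 (adjusted p = 0.0155). The neighbouring genes Ldb3 and Opn4 share 1 set of 17 cytosines, which fell from 46.6% ± 2.55 to 6.15% ± 0.484. Ptprcap and Rps6kb2 have overlapping windows that fell by 42.2 and 36.8 points. Fam151a fell from 85.5% ± 2.56 to 43.5% ± 4.50, and Mfap5, Kcne4 and Heatr9, the rest of the 12 largest losses, fell by 33.8 to 37.2 points.

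The largest gains at gene ends were at B3gnt3, a glycosyltransferase (chromosome 8, 71701626 to 71703626), from 14.2% ± 0.268 to 47.5% ± 2.11 (adjusted p = 0.000425), and Mab21l2, a developmental regulator, from 10.9% ± 3.79 to 41.6% ± 0.499 (adjusted p = 0.000283). Its relative Mab21l1 rose from 30.1% ± 2.52 to 55.6% ± 2.47. Cyp26b1, which degrades retinoic acid, rose from 49.4% ± 1.07 to 77.6% ± 2.92, and Sstr3, a somatostatin receptor, from 31.7% ± 2.96 to 56.7% ± 3.04. The glycolytic enzyme genes Gpi1 and Tpi1 rose from 0.441% ± 0.0493 to 26.9% ± 1.41 and from 0% to 21.1% ± 4.74. At the cytosines that rose in these 2 windows, read depth in P18 relative to the rest of the window was 1.74 times (Gpi1) and 2.64 times (Tpi1) that in P2. Vamp9, Dcaf12l2, Henmt1, Veph1 and AA467197 gained 20.4 to 24.8 points.

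Few list members were called at gene ends. The myelin list had 2 of 35 lower (Mag and Mobp), the oligodendrocyte progenitor list 1 of 33 higher (Matn4, from 10.4% ± 1.77 to 23.3% ± 0.265), and the astrocyte list 1 of 27 lower (Gpr37l1). Of 41 fatty acid and sphingolipid genes 2 rose: Acacb, from 23.2% ± 1.14 to 41.9% ± 0.205, and Cers1, from 63.3% ± 3.10 to 75.3% ± 0.767. Of 22 germline genes Ddx4 and Rnf17 gained 11.4 and 11.7 points and Tdrd9 fell from 89.6% ± 0.434 to 61.7% ± 2.36. Of 17 distinct clustered protocadherin windows, Pcdhga11 rose from 11.3% ± 0.0863 to 30.4% ± 0.346 and Pcdha12 fell from 70.3% ± 0.686 to 49.0% ± 2.20. The other lists had 0 called ends: 20 inhibitors of differentiation, 53 cell cycle, 20 cholesterol, 40 neuronal and synapse, 49 neurogenic transcription factor, 7 microglia and immune, 16 endothelial and mural, 36 Hox, 27 imprinted, 18 DNA methylation machinery, 30 histone modifier, 57 Notch and Wnt and 45 cytoskeleton genes. Counts adjusted over the list alone were the same. Camera's direction and the mean differed in sign for the astrocyte, microglia, fatty acid, histone modifier and cytoskeleton lists, and none of these passed the test (smallest adjusted p = 0.712). Camera called small upward shifts for the Hox (adjusted p = 0.00199), neurogenic transcription factor (adjusted p = 0.00419) and endothelial and mural lists (adjusted p = 0.00914), with medians of 0.354, 0.152 and 1.27 points. With an estimated correlation the adjusted p values were 0.630, 0.630 and 0.637. Median levels of these lists, in the same order, were 0.938, 0.371 and 1.48% in P2 and 1.42, 0.549 and 3.52% in P18. The other 16 lists were not called (adjusted p = 0.157 for oligodendrocyte progenitor genes to 0.978 for imprinted genes). The neurogenic and endothelial calls were lost without P2 replicate 2 (adjusted p = 0.161 and 0.268), and the endothelial one also without P18 replicate 2 (adjusted p = 0.0872) and with windows of 2 kb either side (adjusted p = 0.0725).

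Of the fixed lineage genes, the ends of Cnp, Sox10, Olig1 and Olig2 were at or below 1.07% in both groups, and Mbp stood at 2.66% ± 0.251 and 3.63% ± 0.299. Cspg4 had 0.857 and 2.56% in the P2 libraries and 11.4 and 8.24% in the P18 libraries (8.10 points, adjusted p = 0.0126), under the 10-point threshold. The ends of Pdgfra, Plp1, Mog, Myrf, Dnmt1 and Dnmt3a held too few covered cytosines. The count of called ends was 241 without overdispersion, 76 with limma on the log ratio (44 lower) and 28 at a 25-point threshold (21 lower). The dispersion prior from partly methylated features called 56 with all 4 libraries. By the planned test no end was called with any 1 library left out. A difference of at least 10 points in the same direction was kept by 119 to 121 of the 127. The libraries of the groups did not overlap in any of the 127, so the direction could not reverse. These ends were also chosen for their difference in the same libraries, so the kept share does not measure their stability.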

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

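Mitochondrial cytosines were outside every comparison, and methylated reads there stood above the limit that a count of 0 allows (0.00651 to 0.0168% of reads in the 4 libraries). They made up 0.168% (CI 0.113 to 0.239) of reads in P2 replicate 2, 0.336% (CI 0.260 to 0.427) in P2 replicate 3, 0.176% (CI 0.140 to 0.218) in P18 replicate 2 and 0.187% (CI 0.149 to 0.232) in P18 replicate 3, with 17881 to 46077 reads per library. The values of the 2 groups overlapped, and no explanation was tested.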

How the results depend on the processing

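The count of called gene interiors kept within 1.5 times its value under every alternative but the 25-point threshold (123). Counts outside that range elsewhere were, for tiles, 14256 without overdispersion, 4583 with limma and 2763 at 25 points, and for gene ends 241, 76 and 28 under the same 3 settings, 82 with 500 bp windows, 56 with the prior from partly methylated features and 248 over both gene ends. The last 2 settings, and that prior wherever it is named, were chosen after seeing the data. Removing features whose depth ratio lay outside 0.67 to 1.5, also chosen afterwards, left 7545 tiles, 820 interiors and 121 ends.

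The shared replicate numbers did not pair the samples (correlation of deviations -0.00997 over tiles and 0.0557 over gene ends). With a replicate block, cytosines, tiles and ends had 0 calls (7278, 10932 and 561 at an unadjusted p under 0.05) and interiors 634; with the other prior the block gave 0 (66441 unadjusted), 8179, 11 and 720. The clustered protocadherin interiors lost their call with the block (adjusted p = 0.0894). Leaving out 1 library gave 0 to 5475 cytosines, 0 to 9199 tiles, 0 to 40 ends and 569 to 729 interiors over both priors. With the prior chosen afterwards, the counts without P2 replicate 2, P2 replicate 3, P18 replicate 2 and P18 replicate 3 were 0, 57, 3688 and 5475 cytosines (65133, 77512, 51754 and 47322 at an unadjusted p under 0.05), 8132, 9199, 4706 and 4768 tiles, and 28, 31, 40 and 30 ends. With 1 residual degree of freedom the prior of the planned fit had under 3 degrees of freedom for cytosines, tiles and ends, against 80.3, 15.1 and 7.15 with 4 libraries, and the lone sample of a group is assumed to vary like the other group.

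The list counts (6 for interiors, 3 for ends) became 0 and 0 with an estimated correlation, 1 and 0 with fry, and 5 to 7 and 1 to 3 with a library left out. The estimated correlation was 0.0117 for cholesterol interiors and 0.0268 for neurogenic interiors, near the preset 0.01. Correlation between genes alone therefore does not account for the lost calls of these lists. The other called interior lists had higher estimates, up to 0.701 for the clustered protocadherins. The mean difference was 0.0768 points when weighted by reads, -0.414 over each library's own cytosines with at least 10 reads, and 0.845 over its own cytosines at any coverage (chosen afterwards). Over shared cytosines it was 0.198 to 0.342 with a library left out. Over own cytosines no library was left out, and the library means of the groups overlapped. The intergenic odds ratio of rising cytosines (0.977, not past the test) was 1.03 at a coverage minimum of 20, 1.07 at 10 points and 1.43 against cytosines whose P2 level left room to rise by 25 points, a background chosen after seeing the data. Every other class kept its side of 1 with that background. The Cnp end was at -11.3 points with 2 kb windows, which reach into the interior. No other named gene that passed the test under either setting changed sign. Among genes that did not pass it, the interior differences of Cspg4 (-2.77 to 0.197), Dnmt1 (-1.45 to 5.09), Dnmt3b (-2.88 to 3.11) and Tet1 (-2.63 to 0.640 points) spanned 0 with a library left out. Where no construction is given, the cause was not tested. At the real coverages and a shared overdispersion, the test on simulated data recovered 6 of 100 changes of 30 points at single cytosines. What read depth alone contributes was not tested.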

Other observations

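The counts of tiles per gene, the values of single loci and the tests on neighbours at other CpGs were chosen after the results were seen. Genes with many called tiles included several outside the lists. Agap1, a regulator of membrane traffic, had 14 of 59 tested tiles lower and 2 higher in P18 oligodendrocytes, and Mbp had 10 of 19 lower and 1 higher. Ncor2, a nuclear corepressor, had 10 of 48 lower, and App, the amyloid precursor protein, had 9 of 17. Aatk and Lims2 had 7 of 9 and 7 of 10 lower, and Sema4d, an axon guidance protein of oligodendrocytes, had 7 of 19, and these 5 genes had 0 higher. The annotated span of Lims2 holds the Gpr17 interior, whose fall is given above, so its lower tiles can be those of Gpr17. Other genes had many tiles that rose. Msi2, an RNA-binding protein of neural progenitors, had 13 of 45 tiles higher and 4 lower, Prdm16 had 11 of 74 higher and 3 lower, and Zfp423 had 8 of 43 higher and 1 lower. Pax6 had 6 of 14 and Otx1 5 of 7 higher, with 0 lower. Gse1 had 22 higher and 9 lower of 123.

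The ribosomal RNA-like locus Rn18s-rs5 (chromosome 17, 39846354 to 39848202), on which reads of the repeated ribosomal genes can collect, stood at 12.6% ± 1.99 in P2 and 22.3% ± 0.240 in P18 (SD, n = 2) over 117 cytosines, with 217725 to 262374 reads per library (exact permutation p = 0.333, the smallest possible). The cytosine with the most reads in every library (chromosome 2, 98666504) stood at 88.9% ± 1.23 and 90.6% ± 0.161.

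The called cytosines were weighed against technical explanations. With 4 libraries there are only 3 splits into 2 and 2, too few for a share under 0.05. The real split gave 23433 calls, and the highest of the others was 0 by the same quasi-binomial test (25308 and 23993 at an unadjusted p under 0.05, against 113513). Each of the others puts 1 P2 and 1 P18 library in each group, so a difference between the stages raises the dispersion there. The contrast in calls therefore cannot decide whether the grouping arose by chance. Incomplete bisulfite conversion in one group would shift unmethylated cytosines too, but over 216808 cytosines under 5% the median difference was 0.0193 points. A strain variant at a single CpG would leave its neighbours in place, but for the 15597 called cytosines with at least 2 neighbours within 100 bp the median neighbour difference in the direction of the call was 22.0 points, and it was 21.6 points for the 15175 with 2 such neighbours at other CpGs, that is without the opposite strand of the same CpG, which a variant would move too. For the 1729 whose neighbours moved by under 5 points, the fullest 5% of 1 Mb bins held 35.6%, between the bounds set beforehand, against 15.8% of tested cytosines in the same bins and 33.9% of calls with moving neighbours in their own fullest bins (36.7, 15.5 and 34.2% for neighbours at other CpGs), so strain variants and a change with age or cell type cannot be told apart there.

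A second pattern was a gain at gene ends under 5% in P2, such as Gpi1 and Tpi1. A candidate explanation is extra methylated copies of these sequences in the P18 libraries, such as retrocopies or duplications, whose reads map to the same place. Over the 22 such ends that could be tested, the depth at risen cytosines relative to the rest of the window was 1.18 times higher in P18 at the median, between the bounds set, where the gain itself would need 1.56. The ends split: it was 1.2 or more at 10, among them Cdv3 (5.28), Tpi1 (2.64), Smarca5 (2.24), Gpi1 (1.74), Cyb5b (1.73), Psat1 (1.66) and Nfs1 (1.39), and under 1.1 at 9, among them Cspg4 (1.03) and Tnrc18 (1.01). For the tiles called higher as a whole, the depth ratio was 0.951 times that of matched tiles, which argues against extra copies as their general cause. Tiles called lower stood at 1.07 times matched tiles, so depth tended to move against methylation. That tendency could hide a smaller rise in depth. Extra copies stay open for single ends and tiles, and a change with age or cell type was not tested apart from them.

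Another pattern was the Y chromosome, which took 0.0600 and 0.0566% of reads in the P2 libraries and 0.159 and 0.197% in the P18 libraries. The excess lay between 90 and 91 Mb (0.0442 and 0.0341% against 0.144 and 0.175%), while the rest of the Y took 0.0158 and 0.0225% in P2 and 0.0150 and 0.0217% in P18. More male animals in P18 would lower X-linked gene ends of 5 to 50% methylation, but their median difference was 2.59 points over 344 ends, above the 1.05 of matched autosomal ends (0.395 to 1.79 over 10000 random lists). From 90731001 to 90808000 on the Y, depth was 4.16 times higher in P18 and methylation went from 78.9% ± 0.195 to 88.2% ± 1.16, so a higher copy number of this stretch stays open and was not tested.

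A stretch of chromosome 9 (123923604 to 123927227, next to and within the long noncoding RNA gene Gm51701) had 6.54 times the depth in P18 libraries, and went from 7.36% ± 0.934 to 82.1% ± 0.819 methylation. The tile from 123923001 rose by 52.2 points at a depth ratio of 1.08, and nearby the tile from 123933001 fell by 23.0 points at a ratio of 17.9. Around the tRNA gene n-TGgcc4 on chromosome 1 (171044985 to 171045055), the tiles on either side of 171045001 rose by 53.8 and 52.9 points, with P18 to P2 depth ratios of 2.29 and 0.902. A check of read depth over Plp1, whose promoter drives the P18 reporter, was planned and could not be made, because no cytosine in it passed the coverage minimum.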
